A study of Mus musculus with 72 samples.

How the data were processed

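White adipose tissue, labelled eWAT, of mice was profiled by RNA sequencing in 72 samples. Per the labels, the samples fall into 3 genotypes (WT, LRE and a full-body Bmal1 knockout, here KO), 6 zeitgeber times (ZT 0, 4, 8, 12, 16 and 20 h) and 4 replicates per genotype and time, which makes 18 groups. Bmal1 is a transcription factor of the core circadian clock. The labels do not expand LRE. In earlier work with such mice, a liver-reconstituted animal lacks Bmal1 except where it is restored in hepatocytes; whether LRE stands for this is not stated in the sources used here. The series text names Smart-seq3, a full-length cDNA method whose 5' reads carry molecular identifiers, and describes a hepatocyte cell line in place of tissue; the sample labels were followed here.

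The authors deposited 1 table of whole-number counts with 32377 rows and 180 columns. Each sample was tied to its column by the plate position in its labels and in the column name. The remaining 108 columns match none of these samples and were not used here. Per the submitters' processing notes, reads were aligned with STAR 2.5.4b, and the builds named are mm10 and GRCm38. Per the file headers, the counts came from sorted, deduplicated alignments. The counter, the gene annotation, the use of strand and whether molecular identifiers entered the deduplication are not given in the sources used here. The rows carry no gene or feature identifier, and no row was given a name from its place in the table. A feature is therefore called by its row number, counted from 1 after the header, for at most 2 features that were higher and 2 that were lower. The Bmal1 level, the 33 gene lists and the set tests fixed before the data were examined need identifiers and are not reported here, so the knockout label was not checked against the counts. Rows that hold no gene, if any, could not be told from genes and stayed in the library sizes.

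Library totals ran from 5293 to 508821 counts with a median of 86032. A single count equals 11.6 CPM (counts scaled to a common library total) at the median total, 189 CPM in the shallowest library and 1.97 CPM in the deepest. Of the 24184 rows with any count in the 72 libraries, 3724 were tested; they held a median of 80.5% of a library's counts, with a range of 55.1% to 87.4%. Within groups, all 108 pairs of libraries were compared by the chi-square per degree of freedom over rows with at least 10 counts in the pair. The lowest value was 1.29 and the highest 39.5, so no pair was taken as 1 library. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples.

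Counts were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, after filterByExpr on the 18 groups (minimum count 10, minimum total 15) and TMM scaling, with Benjamini-Hochberg adjustment over the tested rows and an adjusted p threshold of 0.05. Levels were compared in a fit of 18 group means with 54 residual degrees of freedom. The comparison was the mean over the 6 times in one genotype minus that in another. Where no WT library of ZT16 was kept, levels against WT were averaged over the other times. Rhythms were tested in a cosinor fit with a period of 24 h and its own intercept, cosine and sine for each genotype, by an F-test of both rhythm terms, and differences of rhythm by an F-test that both terms are equal. The period was assumed, since 1 cycle was sampled. Amplitude is the height of the fitted peak over the intercept on the log2 scale. The standard error of a log2 fold change was taken as its size over the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Among tested rows, 403 had at least 1 group with no count. A fitted fold change of such a row depends on the prior count, and a row with an empty group in both genotypes compared cannot be tested well; there were 244 such rows for KO and WT and 285 for LRE and WT.

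Named features followed a rule fixed before the data were examined. It took the largest absolute log2 fold changes among rows past the threshold, with a mean log2 CPM of at least 1 and the same direction at all 6 times, and was applied to KO and WT and stopped at 2 features in each direction. The feature with the smallest p was singled out after its values were seen. The tests were checked on simulated counts for the 3724 rows. For KO against WT, 50 of 50 rows changed by a log2 fold of 2 and 49 of 50 changed by 1 were recovered, as were 50 of 50 at -2 and 36 of 50 at -1, with 11 calls among 3524 unchanged rows. For rhythm in LRE, 66 of 100 rows with a log2 amplitude of 1 and 9 of 100 with 0.5 were recovered, with 2 calls among 3524 unchanged rows. Simulated counts were drawn independently for each row, without variation shared by rows or libraries of unusual composition. Recovery and false calls in the real data may therefore differ.

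Alternatives fixed before the data were examined were RLE and upper-quartile scaling, 2 other count filters, other thresholds, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, time as 6 levels, fits of only the genotypes compared, and leaving out each library or replicate number. Chosen after seeing the data were fits without the 4 WT libraries of ZT16, without ZT16 in every genotype, and without 7 libraries that stood apart (a total under 10000 counts, or under 10% or over 30% of counts on the 10 largest rows; these bounds were also set after seeing the data). Also added were fits with a library score as a covariate, on 71 libraries thinned to 30000 counts, and, for LRE and WT levels, with genotype, time and position number as additive terms. Peak times were shuffled over features in 10000 draws. Since a group of 3 loosens the count filter, fits without a library or replicate number were also run on the 3724 rows. The score is each library's projection on the first axis of variation within groups, which held 28.6% of that variation. Comparisons that share the WT libraries were set beside 5 simulations of unchanged groups and beside fits with the WT libraries split.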

Results

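Transcript counts in white adipose tissue were compared between WT, LRE and KO mice over the day, in 4 libraries for each genotype and zeitgeber time. The series title concerns the liver clock and rhythms in white adipose tissue. The comparisons therefore ask how levels and 24 h rhythms in this tissue differ between WT and KO, and where LRE falls. Library totals ranged from 34098 to 508821 counts in WT (median 116104, n = 24), from 34595 to 195757 in LRE (median 92614, n = 24) and from 5293 to 165344 in KO (median 69724, n = 24). The median number of rows with a count was 10939 in WT, 10223 in LRE and 10175 in KO.

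In all, 7 libraries stood apart from the rest. The 4 WT libraries of ZT16 spread their counts over more rows than other groups, with 16360 ± 2250.8 rows detected (SD, n = 4) and 5.99% ± 2.54 of counts on the 10 largest rows. Their median rank correlation with the other libraries lay between -0.01 and 0.32, against 0.71 on average at ZT0 in WT and 0.74 at ZT4. The lowest library of LRE ZT16 (0.25) and of KO ZT16 (0.32) lay in this range, and those of KO ZT8 (0.36), KO ZT4 (0.37) and WT ZT20 (0.37) lay just above it. In WT ZT12 replicate 2 the 10 largest rows held 37.8% of counts, and in WT ZT20 replicate 4 they held 54.01%. KO ZT16 replicate 1 had 5293 counts. Libraries also varied within groups along 1 main axis. The score on this axis was low in all 4 LRE libraries at ZT8 (-0.95 ± 0.03, SD, n = 4) and ZT12 (-0.99 ± 0.16) and higher at ZT16 (1.11 ± 1.09) and ZT20 (0.59 ± 1.15). In KO it was high at ZT8 (0.98 ± 0.95) and low at ZT20 (-0.96 ± 0.04). The highest group mean was that of WT at ZT16 (1.21 ± 0.57), while the means of WT at the other times were negative. WT libraries carried position numbers 1 and 2 on the plate, LRE 2 and 3, and KO 4 and 5. At no time did WT and KO share a number, so position and genotype cannot be told apart for these 2. The same holds for LRE and KO. Position also ran with time. From ZT0 to ZT12 WT had number 1 and KO number 4, and at ZT16 and ZT20 they had 2 and 5. LRE had number 2 at ZT0 and ZT4 and number 3 at the later times. A position effect could thus enter the rhythm counts, which was not tested. WT at ZT16 and ZT20 and LRE at ZT0 and ZT4 shared number 2.

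**Figure D1:**
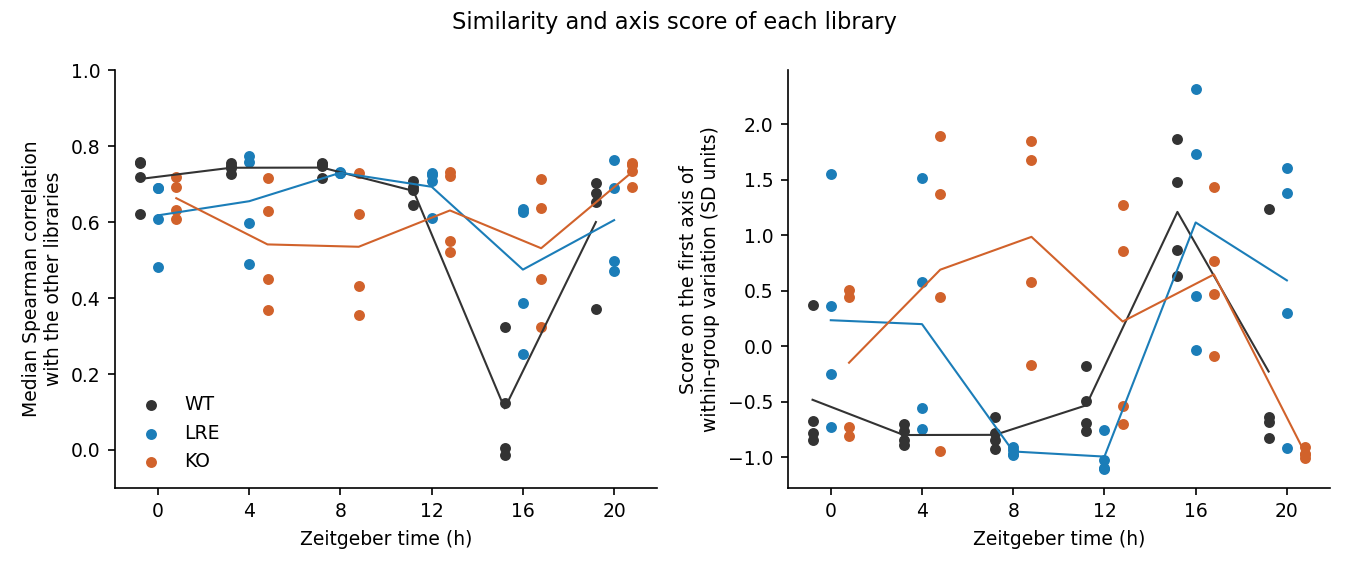
Each point is a library, plotted by zeitgeber time in h; lines join group means. The left panel gives the median Spearman correlation of its log2 CPM with the other libraries and the right panel its score on the first axis of within-group variation in SD units; the 4 WT libraries at 16 h lie at correlations of 0.32 or lower.

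KO and WT differed in level, averaged over the 6 times, at 849 of 3724 features. Of these, 387 were higher and 462 lower in KO, with a median absolute log2 fold change of 0.80 (edgeR quasi-likelihood F-test, adjusted p under 0.05). At least a 2-fold change was seen for 285. The direction was the same at all 6 times for 259 of the 849, 121 of them higher and 138 lower. The feature with the smallest p was lower in KO by a log2 fold change of -2.81 ± 0.26 (SE, adjusted p = 1.61e-12 by edgeR). Its level in WT was 1186 ± 454 CPM (SD, n = 4) at ZT0, 834 ± 106 at ZT4 and 1271 ± 476 at ZT12. In KO it was 112 ± 25 CPM at ZT0, 83.7 ± 79.6 at ZT4 and 107 ± 40 at ZT12. At ZT16 the WT level was 104 ± 95 CPM and the KO level 37.5 ± 28.9 CPM.

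The features with the largest fold changes were present in some libraries and nearly absent in others. The feature in row 2038 was higher in KO (adjusted p = 2.92e-06 by edgeR), with counts in 23 of 24 KO libraries and 4 of 24 WT libraries. Its median was 1209 CPM in KO and 0 in WT. Within KO at ZT16 it ran from 205 to 22271 CPM. At ZT20 it averaged only 24.9 ± 18.8 CPM in KO (SD, n = 4) and 41.4 ± 82.8 in WT. The same direction at all times refers to mean log2 CPM. In LRE it had counts in 15 of 24 libraries, with a median of 37.0 CPM and a highest of 14239 CPM. Also higher in KO was the feature in row 24202 (adjusted p = 3.18e-05), with counts in 21 of 24 KO and 7 of 24 WT libraries. Lower in KO was the feature in row 15644 (adjusted p = 0.00707), with counts in 2 of 24 KO and 12 of 24 WT libraries. It reached 107524 CPM in WT ZT20 replicate 4 and 33617 CPM in WT ZT12 replicate 2, and its WT median was 4.09 CPM. This call was lost with limma-voom (adjusted p = 0.217), on thinned counts (1.00), and without WT ZT0 replicate 4 (0.0534), ZT4 replicate 4 (1.00), ZT8 replicate 4 (0.0522) or ZT16 replicate 1 (1.00). In ZT4 and ZT16, that library held the only WT counts, and with the 3724 features kept only these 2 of the single libraries ended the call. So was the feature in row 9806 lower in KO (adjusted p = 0.00983), which reached 177921 CPM in WT ZT20 replicate 4. It did not pass the threshold with limma-voom (0.315), on thinned counts (0.0514) or without the 7 libraries that stood apart (0.0550). Leaving out WT ZT0 replicate 1 (1.00), ZT4 replicate 4 (0.0664), ZT8 replicate 2 (0.0536), ZT8 replicate 4 (0.0530) or ZT20 replicate 4 (0.0567) also ended the call. With the 3724 features kept, ZT0 replicate 1 (1.00), ZT4 replicate 4 (0.0564) and ZT20 replicate 4 (0.0503) did so. Groups with no count, in WT for rows 2038 and 24202 and in KO for rows 15644 and 9806, make these fitted fold changes depend on the prior count.

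The split into higher and lower features depended on the scaling, the tool and the libraries used. With upper-quartile scaling, 538 features were higher and 305 lower in KO. DESeq2 gave 552 and 453, limma-voom 514 and 426, a fit of only the 2 genotypes 425 and 349, and the fit without the 7 libraries 386 and 352. It was 327 and 308 without the 4 WT libraries of ZT16, with ZT16 then out of the averages. Leaving out 1 library turned or evened the split in 60 of 72 fits, with 392 to 575 higher and 323 to 458 lower. A group of 3 loosened the count filter, so these fits tested 4018 to 4537 features. With the 3724 features kept, 21 of 72 did so, with 333 to 476 higher and 335 to 497 lower. The median log2 fold change of all features was -0.06 with TMM and 0.05 with upper-quartile scaling. By time point, 4 against 4, KO and WT differed at 22 features at ZT0, 264 at ZT4, 330 at ZT8, 29 at ZT12, 1376 at ZT16 (954 of them lower in KO) and 229 at ZT20. Higher in KO were 192 of those at ZT4 and 258 of those at ZT8, while 166 of those at ZT20 were lower. The fit without the 7 libraries held no WT library of ZT16, so levels were averaged over the other times. There 738 of 3359 features differed, and 476 of these were among the 849, all 476 in the same direction.

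LRE and WT differed in level at 601 features, 249 higher and 352 lower in LRE, with a median absolute log2 fold change of 0.84 (edgeR, adjusted p under 0.05). With upper-quartile scaling, 389 were higher and 236 lower. Leaving out 1 library turned or evened it in 16 of 72 fits, the most without WT ZT16 replicate 1 (461 higher and 274 lower). With the 3724 features kept, 13 of 72 fits did so, with 221 to 308 higher and 265 to 406 lower. The direction was the same at all 6 times for 229. The feature with the smallest p was the same as in KO, at a log2 fold change of -2.98 ± 0.25 (SE, adjusted p = 8.40e-14 by edgeR). In LRE it stood at 149 ± 90 CPM (SD, n = 4) at ZT0, 56.5 ± 24.1 at ZT4 and 134 ± 42 at ZT12. At ZT20 it stood at 51.6 ± 5.5 CPM in LRE and 129 ± 58 in KO. The highest of the 24 LRE libraries stood at 281 CPM. By time point the counts were 64 at ZT0, 87 at ZT4, 11 at ZT8, 145 at ZT12, 1253 at ZT16 (912 of them lower in LRE) and 194 at ZT20. A total of 553 of 3359 features differed from WT without the 7 libraries, averaged over the times other than ZT16. With time and position number as additive terms, which assumes the same genotype difference at all times, 1092 features differed, 563 higher and 529 lower. That fit gave 820 without the 7 libraries, 596 higher and 224 lower.

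Both comparisons called 440 features, 177 higher and 263 lower in both, and none in opposite directions. Independent lists of these sizes would share 25.9 higher and 43.7 lower features. Fold changes of KO and of LRE against WT correlated across features at r = 0.95, with a covariance of 0.83. The 326 features with an empty WT group enter both values, and their fold changes depend on the prior count. The sign was the same in both comparisons for 82.2% of all features. Features are not independent replicates, and both comparisons use the same WT libraries. Unchanged simulated groups gave r = 0.46, a covariance of 0.03 and the same sign for 65.5% of features on average. Their counts were drawn independently for each feature, without the within-group axis or the libraries that stood apart. They do not show how high these values can be in unchanged groups with that structure. With replicates 1 and 2 of WT set against KO and the others against LRE, r was 0.85, the covariance 0.83, and 165 features were called in both, all in the same direction. With the WT libraries exchanged, r was 0.86 and 150 were called in both.

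**Figure D2:**
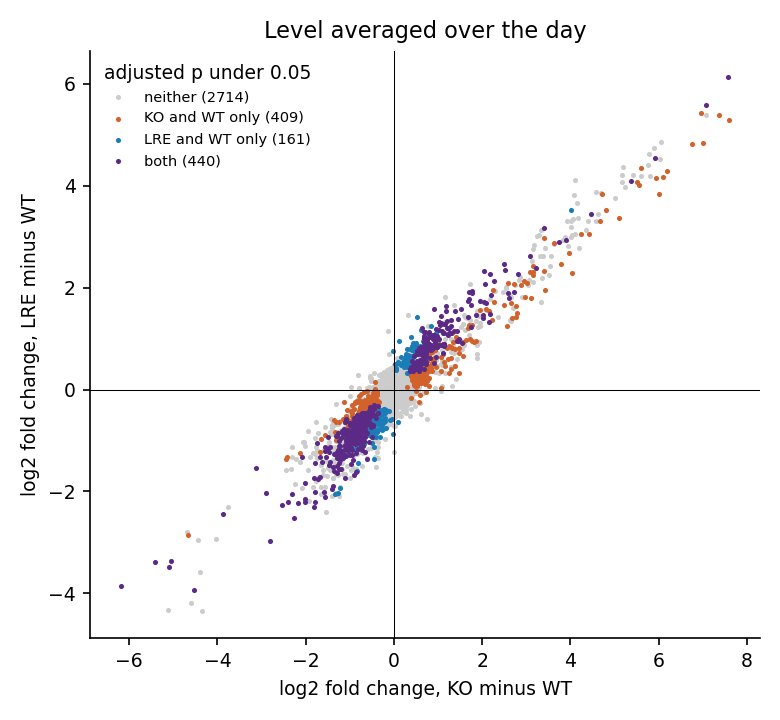
Each point is a tested feature, with the log2 fold change of KO minus WT on the horizontal and LRE minus WT on the vertical axis, averaged over the day. Colours mark features past an adjusted p of 0.05 in one, both or neither comparison; the 440 called in both lie in the lower left and upper right.

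LRE and KO did not differ in level at any feature by edgeR (adjusted p under 0.05). At an unadjusted p under 0.05 there were 283 features, where 186 are expected by chance. DESeq2 called 23 and limma-voom 0. By time point, the 4 against 4 comparison called 394 features at ZT8, 346 of them lower in LRE, then 22 at ZT12 and 218 at ZT20, 209 of them higher in LRE. It called 0 at ZT0, ZT4 and ZT16. The axis score moved the same way, lower in LRE at ZT8 and higher at ZT20.

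**Figure D3:**
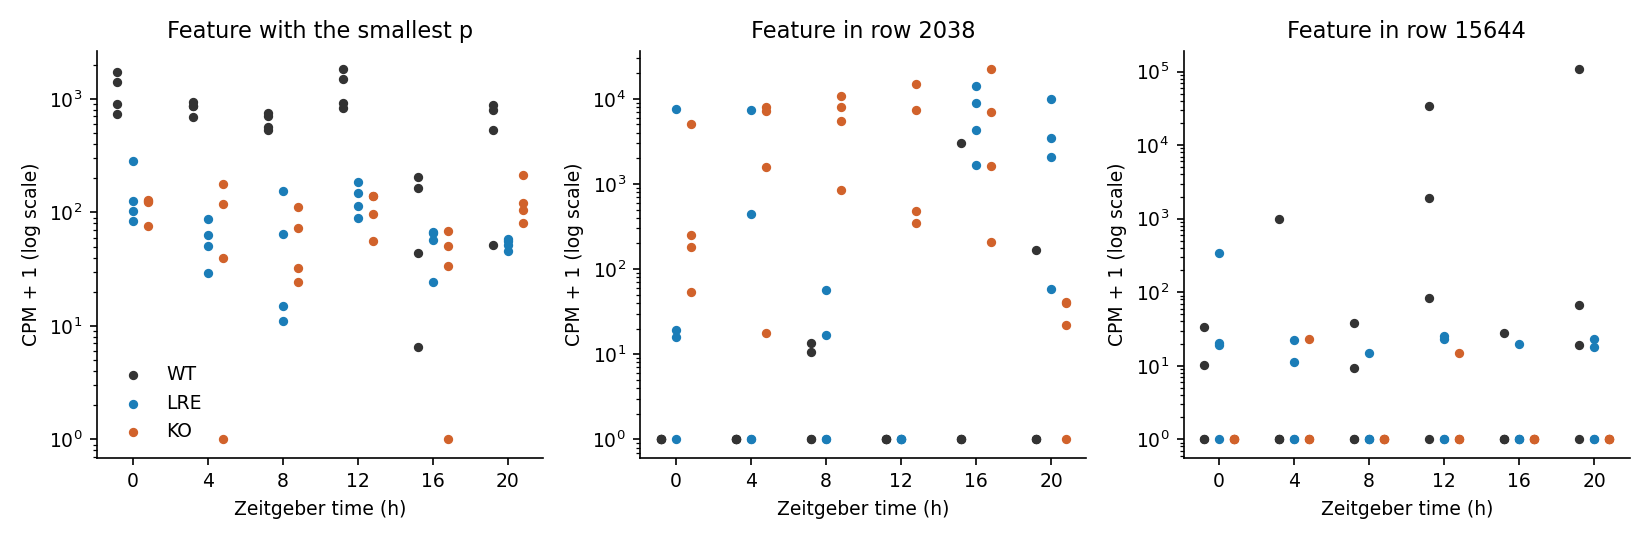
Each point is a library, with zeitgeber time in h on the horizontal axis and CPM plus 1 on a log scale on the vertical axis, for the feature with the smallest p and the features in rows 2038 and 15644. The first reaches at most 281 CPM in LRE and 213 CPM in KO, while the others range from 0 to 22271 and 107524 CPM.

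In WT, 1718 of 3724 features were rhythmic with a period of 24 h (edgeR F-test, adjusted p under 0.05). Their median amplitude was 1.02 on the log2 scale, a peak-to-trough ratio of 4.10. Peaks of 920 features fell between ZT16 and ZT20 and of 289 between ZT4 and ZT8. This count rested on ZT16. Without the 4 WT libraries of ZT16 it was 142, of which 138 were among the 1718, and without the 7 libraries that stood apart it was 83, of which 74 were. In LRE 268 features were rhythmic, with a median amplitude of 1.07, and 193 of them peaked between ZT20 and ZT24. The LRE count was 507 without the 7 libraries, of which 6 were WT, 1 was KO and none was LRE. With the axis score in the fit over all libraries it was 92. Leaving out single libraries gave 96 (without LRE ZT20 replicate 2) to 584 (without LRE ZT4 replicate 1). Without replicate number 1, 2, 3 or 4 the count was 379, 5, 57 or 30. In KO 55 features were rhythmic, with a median amplitude of 1.30; the count was 25 with the axis score, 77 without the 7 libraries and 0 without replicate number 2. Without ZT16 in every genotype it was 383, against 178 in WT.

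**Figure D4:**
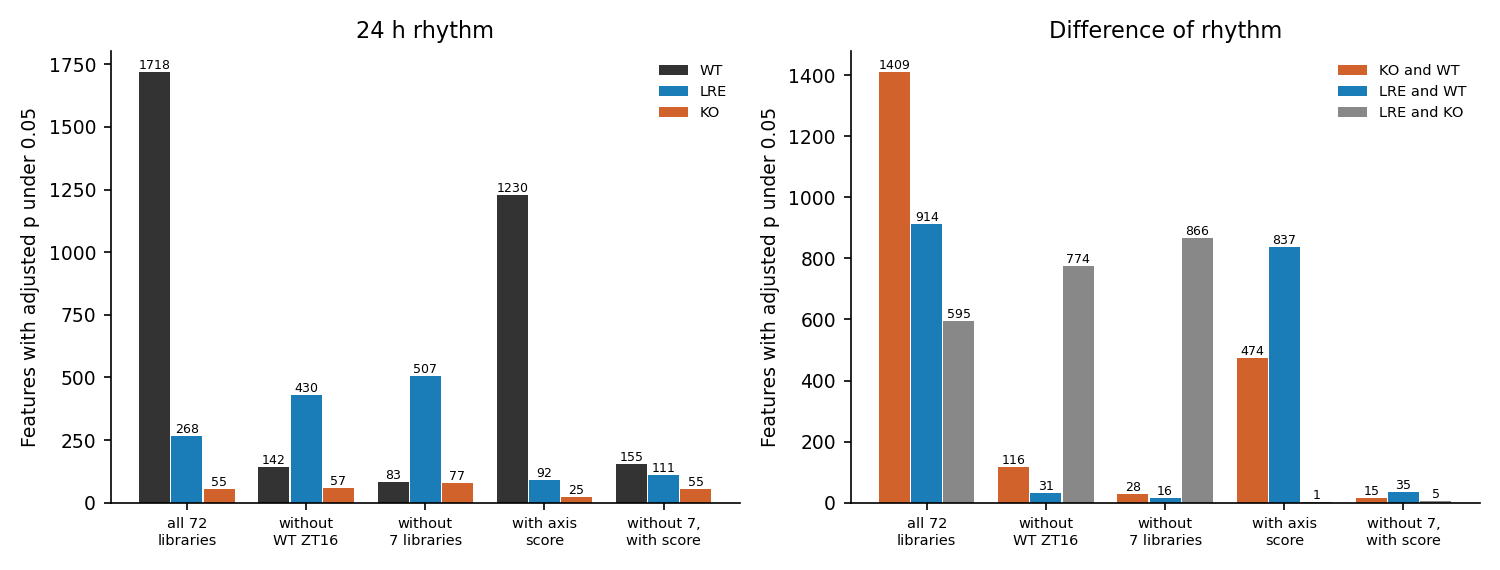
Bars give the number of features past an adjusted p of 0.05 for a 24 h rhythm in each genotype (left) and for a difference of rhythm between genotypes (right), in all 72 libraries and in 4 fits chosen after seeing the data. The WT bar falls from 1718 to 142 without WT ZT16, and the LRE and KO difference from 595 to 1 with the axis score.

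Rhythms differed between KO and WT at 1409 features, between LRE and WT at 914 and between LRE and KO at 595 (edgeR F-test, adjusted p under 0.05). Without the 4 WT libraries of ZT16, the counts against WT were 116 for KO and 31 for LRE, while 774 features differed between LRE and KO. With the axis score over all libraries, 474 features differed between KO and WT, 837 between LRE and WT, and 1 between LRE and KO.

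Features rhythmic in both WT and LRE numbered 128, where independent lists would share 124. Of these, 90 also differed in rhythm from KO in both genotypes. With the axis score this number was 0 and without the 7 libraries it was 9. It was 0 without replicate number 2 and 135 without replicate number 1. The 128 features peaked later in LRE than in WT by a circular median of 3.36 h, with quartiles at 1.76 and 4.48 h. Of these, 31 peaked within 2 h of their WT time (24.2%) and 76 within 4 h (59.4%). With the LRE peak times shuffled over these features, the averages were 16.1% (95% of shuffles between 10.9% and 21.1%) and 38.1% (32.0% to 44.5%). Features that rise and fall together are not independent, so such shuffled ranges are descriptive and give no p-value. Without the 7 libraries, 32 features were rhythmic in both, where 12.5 are expected, and 62.5% of them peaked within 2 h (38.2% when shuffled, 25% to 50%), at a median difference of -0.24 h.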

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

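The fits with the axis score as a covariate, the tests of the axis in WT ZT16 and of depth for the LRE and KO rhythms, and the counts of splits were chosen after the result was seen. The remaining tests were stated before, the permutation of the score among them, although the score itself was added after seeing the data. For the position fit, the quartiles were added to the bound after its values were seen.

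Rhythms differed between genotypes by tests of the difference itself, at 1409 features for KO and WT, 914 for LRE and WT and 595 for LRE and KO. In fits without the 7 libraries the counts were 28, 16 and 866, and with the axis score 474, 837 and 1. Single libraries lay far from the other 3 of their group in 7 of 72 sets of 4 library measures, where chance gives about 1 in 20, or 3.6. They did so in 34 of 90 sets of 4 feature values. In 18 of these the other 3 values were 0, so the rate of 1 in 20 does not apply to features with so few counts. KO ZT0 replicate 3 had 46836 counts and KO ZT16 replicate 1 had 2491 rows detected. The 10 largest rows held 37.8% of counts in WT ZT12 replicate 2, 54.01% in WT ZT20 replicate 4 and 18.6% in KO ZT12 replicate 2. The axis score was 0.37 in WT ZT0 replicate 4 and 1.24 in WT ZT20 replicate 4.

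The feature in row 2038 stood out at 3042 CPM in WT ZT16 replicate 4, 165.6 in WT ZT20 replicate 1, 7549 in LRE ZT0 replicate 4, 7335 in LRE ZT4 replicate 1 and 5060.1 in KO ZT0 replicate 1. That in row 24202 did so in the same libraries, at 1037, 18.4, 6333, 5941 and 2905 CPM, and at 5.52 in WT ZT0 replicate 3 and 8.19 in WT ZT8 replicate 1. That in row 15644 stood out at 982 CPM in WT ZT4 replicate 4, 33617 in WT ZT12 replicate 2, 27.2 in WT ZT16 replicate 1 and 107524 in WT ZT20 replicate 4. In LRE it did so at 338 in ZT0 replicate 1, 18.7 in ZT16 replicate 4 and 14.0 in ZT8 replicate 1, and in KO at 22.2 in ZT4 replicate 3 and 13.8 in ZT12 replicate 3. That in row 9806 did so in WT at 18.8 in ZT0 replicate 1, 501 in ZT4 replicate 4, 34430.3 in ZT12 replicate 2 and 177921 in ZT20 replicate 4. In LRE its values were 191 in ZT0 replicate 1, 66.4 in ZT12 replicate 2, 10.1 in ZT8 replicate 3 and 11.1 in ZT20 replicate 4. In KO they were 18.7 in ZT0 replicate 1, 19.4 in ZT4 replicate 4, 17.8 in ZT8 replicate 2 and 41.3 in ZT12 replicate 3. The feature with the smallest p stood out at 75.0 CPM in KO ZT0 replicate 1. Many of the values under 50 CPM rest on 1 or a few counts.

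The 4 WT libraries of ZT16 stood apart and carried most rhythm calls in WT. Unequal totals are argued against as the whole account. At 30000 counts each, over 1422 features, their median rank correlation with the other libraries was -0.0937, with a range of -0.18 to 0.30. The other WT libraries lay between 0.31 and 0.80, and the lowest library of the other genotypes at 0.18. Thinning keeps each library's expected proportions, so a profile difference that came with greater depth would remain. For a change at ZT16 shared by all genotypes, the shift of ZT16 from other times correlated across features at 0.34 between WT and LRE and 0.20 between WT and KO. Only the KO value met the bound set before, and KO ZT16 includes the library of 5293 counts. This argues only weakly against such a change. A shared part along the axis stays open, as the mean score at ZT16 was 1.21 in WT, 1.11 in LRE and 0.65 in KO. The axis that varies within LRE and KO groups remains open, as its loading correlated with the WT shift at 0.47. A change of WT tissue at ZT16, a different piece of tissue or a handling difference of this group may each account for the pattern, and none of these was tested.

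The rhythm difference between LRE and KO may follow the axis of within-group variation, since 1 feature was called with the score as a covariate. The score also differs between groups (R2 = 0.55), so the covariate would remove a biological rhythm that runs along the axis as well. Unequal totals alone are argued against by 390 of 1422 features called on thinned counts. Thinning keeps each library's expected proportions, so a profile difference that came with depth would remain. Chance placement of libraries along the axis is argued against by a permutation p of 0.00018 for the rhythm difference of the score, with LRE and KO labels permuted within each time in 100000 draws. What the axis is, a mix of cell types or dissected tissue or a state of the tissue, stays open without gene names. Position on the plate stays open as well, since LRE and KO shared no position number.

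Level differences from WT went the same way in KO and LRE. Shared WT libraries are argued against as the whole cause, as r was 0.85 or more with the WT libraries split. Both parts kept libraries of WT ZT16, so a deviation common to that group would stay in each. No split was run without them. The axis is argued against too, with 1077 features called in KO against WT once the score was in the fit. On counts thinned to equal totals, KO minus WT fold changes had a median ratio of 0.99 to the full ones over 229 features. The differences of these features thus did not need unequal totals. Random thinning keeps each library's expected proportions, so a profile difference that came with greater depth in WT would remain. Features that thinning left too low to test are not covered, so greater depth in WT stays open. For KO and WT, position on the plate cannot be told apart from genotype, because they shared a position number at 0 of 6 times. LRE and WT shared number 2, at different times. With position as an additive term, LRE fold changes over the 440 features called in both comparisons had a median ratio of 1.34 to the unadjusted ones. Of the 440, 371 kept their sign, but only 183 were called in that fit. Without the 7 libraries the median ratio was 1.1215, and of 381 such features 280 kept their sign and 115 were called. Quartiles there were -0.14 and 2.25, and the fit assumes equal differences at all times, so position stays open for LRE too. A lasting difference between WT and both other genotypes may account for the pattern as well.

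How often relabelled samples gave as many features was counted with limma-voom over 100 splits for each result, the real one included. For levels, KO and WT gave 940 features and the highest other split 268, and LRE and WT gave 896 against 335, each as large in 1 of 100 splits. LRE and KO gave 0, reached by 100 of 100 splits with a highest of 6. For rhythm, WT gave 1842 against 1258 and LRE 165 against 158, each in 1 split of 100, and KO gave 45 in 2 splits with a highest of 104. Rhythm differences were 1569 against 733 for KO and WT, 913 against 492 for LRE and WT and 623 against 174 for LRE and KO, each in 1 split. The joint count was 37 in 1 split against 0, which decides nothing, since it needs 4 calls at once and relabelled times leave few rhythm calls. In fits of all 72 libraries, chance alone is argued against except for the level of LRE and KO and the joint count. It is so only weakly for the KO rhythm, where another split gave 104, and for the LRE rhythm, where another gave 158. With the 7 libraries left out, the LRE and WT rhythm difference of 10 was reached by 6 splits of 100.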

How the results depend on the processing

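The fits without doubted libraries, without ZT16, with the axis score, with the position number, on thinned counts and, with a library left out, on the 3724 features of all 72 libraries were chosen after seeing the data; all others were fixed before the data were examined. The Bmal1 level and the gene lists were not run under any alternative, because the rows carry no identifiers. Causes were not tested except where the setting itself changes the number of features tested, of libraries or of counts. The filter at 1 CPM in 36 libraries kept more features than the main filter, since 1 count exceeds 1 CPM in every library. RLE scaling and the amplitude minimum moved no count by over 1.5 times.

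Level calls between KO and WT numbered 849, and 424 at an adjusted p under 0.01. They numbered 285 with at least a 2-fold change and 229 on thinned counts, where 1422 features were tested. For LRE and WT the count of 601 became 324, 205 and 179 in the same settings, and 961 with cosinor intercepts. Higher and lower calls turned from 387 and 462 to 538 and 305 between KO and WT with upper-quartile scaling, and from 249 and 352 to 389 and 236 between LRE and WT; DESeq2 gave 552 and 453 in KO and 444 and 363 in LRE, and limma-voom 514 and 426 in KO and 369 and 527 in LRE. With the position number as a term, LRE and WT differed at 1092 features, and at 820 without the 7 libraries as well. Between LRE and KO the count of 0 became 12 without a count filter, 23 with DESeq2, 1 without ZT16, 1 without the 7 libraries, 2 with the axis score and 25 with both. Leaving out a library or a replicate number gave 490 to 964 for KO and WT, 259 to 735 for LRE and WT and 0 throughout for LRE and KO. No single library moved these totals by over 1.5 times. Higher and lower calls for LRE and WT moved by more without WT ZT0 replicate 1 (363 and 231), WT ZT16 replicate 1 (461 and 274), WT ZT20 replicate 4 (411 and 267) and KO ZT16 replicate 2 (396 and 263). Fits without a single library tested 4018 to 4537 features; on the 3724 features no single library moved either number by over 1.5 times.

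Without a count filter, 24184 features were tested in place of 3724. Rhythmic features then numbered 8054 in WT, 765 in LRE and 503 in KO. Rhythm differences numbered 4028 for KO and WT, 2763 for LRE and WT and 1147 for LRE and KO. The joint count of features rhythmic in WT and LRE and different from KO was 386. With the 1 CPM filter, which left 10325 features to test, the rhythm counts were 3241, 160 and 32 and the joint count 38. At an adjusted p under 0.01 they were 58 in LRE and 16 in KO, with differences of 827, 530 and 168 and a joint count of 13; at 0.1 the joint count was 214. With limma-voom 165 features were rhythmic in LRE and the joint count was 37. Time as 6 levels gave 534 in LRE and 18 in KO, and a fit of LRE alone 93. Thinned counts, with only 1422 features tested, gave 462 in WT, differences of 437, 240 and 390 and a joint count of 49. Counts from fits that tested unlike numbers of features do not compare as shares.

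Without WT ZT16, counts were 142 in WT and 430 in LRE, differences from WT 116 and 31, the joint count 22 and the median phase difference 0.0597 h against 3.36 h. Without ZT16 in every genotype they were 178, 626 and 383, the differences 397, 81 and 894, the joint count 50 and the phase difference 1.99 h. Without the 7 libraries they were 83 in WT and 507 in LRE, the differences from WT 28 and 16, the joint count 9 and the phase difference -0.24 h. With the axis score, 92 were rhythmic in LRE and 25 in KO, 474 differed between KO and WT and 1 between LRE and KO. The joint count was 0 and the phase difference -0.36 h. In that fit 42 features were rhythmic in WT and LRE, where 30.4 are expected, and 13 of them (31.0%) peaked within 2 h. Without the 7 libraries and with the score, 155 were rhythmic in WT and 111 in LRE. In that fit the differences were 15, 35 and 5, the joint count 0 and the phase difference 0.99 h.

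Leaving out libraries or replicate numbers gave 1168 to 2444 rhythmic features in WT, 5 to 584 in LRE, 0 to 98 in KO, 583 to 2029 differences for KO and WT, 412 to 1465 for LRE and WT, 62 to 860 for LRE and KO, a joint count of 0 to 211 and a phase difference of 2.28 to 4.40 h. The LRE rhythm count was 584 without LRE ZT4 replicate 1, 508 without ZT0 replicate 3 and 474 without ZT20 replicate 1. It was 137 without ZT0 replicate 4, 107, 156, 123 and 147 without replicates 1 to 4 of ZT8, 138, 132, 136 and 128 without those of ZT12, and 96 and 109 without ZT20 replicates 2 and 3. The joint count moved with the same libraries, between 22 and 211. In KO it was 98 without ZT4 replicate 1, 28 and 90 without ZT8 replicates 1 and 3, 31, 29, 34 and 36 without replicates 1 to 4 of ZT20, and 87 without WT ZT0 replicate 4. Differences for LRE and WT numbered 1465 without WT ZT0 replicate 4 and 1374 without LRE ZT16 replicate 1, and those for LRE and KO 393 without KO ZT8 replicate 4. On the 3724 features, single libraries gave 93 to 582 rhythmic features in LRE, 21 to 80 in KO, 612 to 1065 differences for LRE and WT, 400 to 833 for LRE and KO and a joint count of 21 to 217.

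Where the library left out held the only counts of a WT group (WT ZT4 replicate 4 and ZT16 replicate 1 for row 15644, ZT0 replicate 1 for row 9806), both genotypes then had an empty group and the row could not be tested well. The feature with the smallest p and those in rows 2038 and 24202 passed the threshold in KO against WT under every alternative that kept them. That in row 15644 did not with limma-voom (-1.69) or thinned counts (-5.50), nor without WT ZT0 replicate 4, WT ZT4 replicate 4, WT ZT8 replicate 4, WT ZT16 replicate 1, or replicate number 1 or 4 in all groups. That in row 9806 did not with limma-voom (-1.47), thinned counts (-5.36), without the 7 libraries (-2.79) or with the score as well (-2.20), nor without WT ZT0 replicate 1, WT ZT4 replicate 4, WT ZT8 replicates 2 and 4, WT ZT20 replicate 4, or replicate number 1, 2 or 4 in all groups.

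Replicate numbers did not pair the samples. Over 612 pairs of libraries of different groups that share a number, deviations from group means correlated at 0.00147 on average, and 21 of 72 libraries correlated best with their own number. With the replicate number as a block, 836 features differed between KO and WT, 592 between LRE and WT and 0 between LRE and KO, 1689, 286 and 56 were rhythmic in WT, LRE and KO, 1384, 872 and 590 differed in rhythm, and the joint count was 102.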

Other observations

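The tests in this part were chosen after seeing the data. Without the 7 libraries that stood apart, relabelled samples gave a different picture for rhythms. The LRE rhythm count by limma-voom was 266, equalled or passed by 4 of 100 splits with a highest of 439, and the KO count was 60, with a highest of 379. The WT count was 60 against a highest of 11. Level counts of 603 for KO and WT and 530 for LRE and WT stood against 1 in the highest other split of each. The LRE and WT rhythm difference of 10 features was reached by 6 of 100 splits, so chance was not excluded there. The joint count was 0. The LRE and KO rhythm difference was 857, against a highest of 555. A split of LRE and KO labels called up to 1015 features in level, where the real labels called 1. Splits that call many times the real number point to a structure of the samples, and its nature was not tested.

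Without the 7 libraries and with the axis score, 24 features were rhythmic in both WT and LRE, where independent lists would share 5.12, and 18 of them (75.0%) peaked within 2 h of each other, where shuffled peak times gave 37.1% on average (20.8% to 54.2%). Features are not independent here either, so the shuffled range gives no p-value. In that fit 155 features were rhythmic in WT, 111 in LRE and 55 in KO. That LRE shares the rhythm of the features rhythmic in WT was tested on the mean LRE amplitude along the WT phase. It was 0.264, with a permutation p of 1e-05, the smallest that 100000 draws of LRE time labels can give (adjusted p = 6.0e-05 over 6 tests). In KO it was 0.176 (permutation p = 9.0e-05, adjusted p = 0.00018, n = 23). In both, the draws shuffled times while the score stayed with its library. They therefore lacked the tie of score to time of the real samples, and these 2 p-values may be too small. The LRE minus KO difference was 0.0877 (permutation p = 0.0805, adjusted p = 0.0966, n = 24 and 23), with labels permuted within time. Without the score, over 83 features, LRE stood at 0.624 (adjusted p = 0.00018), KO at 0.00713 (adjusted p = 0.481) and the difference at 0.617 (adjusted p = 0.00112). So a rhythm along the WT phase was seen in LRE in both fits, with that limit on the p-value in the fit with the score. Position on the plate also ran with time. A stronger one than in KO was seen only in the fit without the score and stays open. Both fits used the same libraries and tested features, and only the score was switched. The score entered the choice of features, 155 against 83, as well as the amplitude. Which of these 2 routes carried the change was not tested. These tests follow values already seen, on the same samples.

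In the fit without the 7 libraries, ZT16 was out of the averages against WT. There 403 of 3359 features differed in level from WT in both KO and LRE, all in the same direction. With the axis score over all libraries 652 of 3724 did.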
